A study of Oryza sativa with 15 samples.

How the data were processed

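RNA of rice endosperm was sequenced 5 days after fertilization from hybrids between japonica and indica lines, with 20 to 30 endosperms pooled per replicate. The mothers were cytoplasmic male sterile lines, whose pollen is sterile, and the fathers were maintainer lines, which are fertile and carry the nuclear genome of their sterile partner. The LR cross has the japonica line Liuqianxin as mother and the indica line Rongfeng as father, and RL is the reverse. The YW cross has the japonica line Yu6 as mother and the indica line Wufeng as father, and WY is the reverse. The 15 libraries comprise 3 of LR, 3 of RL, 2 of YW, 2 of WY and 5 of the inbred controls of Liuqianxin and Rongfeng. The allele tables hold no columns of the inbred controls, which were therefore not used here.

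The deposited tables give, for each SNP between the parents, a whole-number count of reads with the maternal allele and of reads with the paternal allele in each cross. Per the file headers there is 1 maternal and 1 paternal column per cross and none per replicate, so the counts are those of the pooled replicates. The authors also deposited a p-value and a false discovery rate per SNP and cross. Recomputed from the counts, the deposited p-value was that of a chi-square test against 2 maternal to 1 paternal, within a relative tolerance of 2%, for 62102 of 62102 SNPs in LR and RL, 59107 of 59107 in YW and 59106 of 59107 in WY. These p-values were not used in the calls. The submitters' processing notes name Trimmomatic 0.32, Bowtie2 2.2.1, SAMtools 0.1.16 and GATK 3.5 without stating an order, and the genome build is not given in the sources used here. Every SNP in the tables has at least 11 reads in each of its crosses, which also limits the loci that can be seen. In the table of LR and RL, 60045 SNPs are listed with the Liuqianxin allele as the reference allele and 2057 with the Rongfeng allele.

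Counts were summed over the SNPs that the tables assign to a locus. A read that covers several SNPs of a locus is then counted at each, and reads of multigene families can align to more than 1 locus. The tested loci had a mean of at least 10 counts per library in both crosses of a set, which is 30 counts per cross in LR-RL and 20 in YW-WY. Endosperm carries 2 maternal genomes and 1 paternal genome, so the null maternal share was 66.7%.

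The edgeR test between replicate libraries that had been fixed beforehand could not be fitted within a cross set, because the replicates are pooled. The alternative fixed with it was used in its place. The pooled counts of each cross were tested with an exact two-sided binomial test against the null share, the larger of the 2 p-values of a set was kept, and these were adjusted over all tested loci by the Benjamini-Hochberg method. A maternal call required an adjusted p under 0.05 and a share above the null in both crosses, and a paternal call a share below it in both. A japonica or indica call required the same p with the shares on opposite sides of the null. A strong call was also at least 5 times from 2:1 in both crosses, which is a maternal share of at least 90.9% or a paternal share of at least 71.4%. These tests cover counting error only: they compare these pooled libraries and cannot generalise over plants. A read counted at several SNPs of a locus enters them more than once, so they can understate even the counting error. Departures from 2:1 were averaged over the 2 crosses of a set on the log2 scale, with 0.5 added to each count.

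After the data had been seen, a joint fit of the 4 crosses was added, in which the 2 cross sets serve as replicates. It used edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test, an offset for the 2:1 dosage, a strain term per set and a common dispersion of 0.0470. It leaves 1 residual degree of freedom per locus, so the spread rests on the value pooled over loci. The calls and the joint fit were tested on simulated data of 9753 loci, 200 of them made parent-biased. The joint fit recovered 50 of 50 loci for each combination of direction and fold (5 or 20), with 20 false calls among 9553 unchanged loci under counting noise and 13 with added spread. Per-set calls recovered at least 48 of 50. Strong calls recovered at least 49 of 50 at 20-fold but only 2 to 8 of 50 at 5-fold, which is their threshold. False calls among the per-set calls numbered 1 in each set under counting noise. They numbered 136 in LR-RL and 144 in YW-WY once a spread of 0.15 (SD of the natural logarithm) was added between crosses. Strong calls had 0 false calls in each setting. Apart from strain effects, unchanged loci were simulated around 2:1 in every cross, with a spread that was chosen and not estimated. In the data the median share was 75.1% in YW, so these false-call numbers do not carry over to the data.

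Sets were compared by the overlap of calls among loci tested in both, with Fisher's exact test (two-sided), by the correlation of effects across loci, and by a test of the difference between sets that covers counting error only. Total counts of both alleles were scaled by the TMM method of edgeR and compared between reciprocal crosses as values without a test, with counting intervals. The fixed gene lists were tested for calls with Fisher's exact test, adjusted over lists, sets and directions. They cover Polycomb repressive complex 2, DNA methylation, auxin synthesis, endosperm MADS-box genes, starch synthesis, storage proteins with their regulators, and sugar import. Markers of green pericarp, nucellus and ovule, embryo and aleurone were examined in the same way. The genes named were chosen by a rule fixed before the data were examined. Per set and direction it takes the 10 calls farthest from 2:1 with at least 20 counts per library, and for both sets together up to 10 loci with strong calls in both. It further takes the 5 largest strain and total differences, and every listed gene.

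Alternatives tried were the median ratio of each cross as null, no minimum count, a mean of at least 50 counts, the SNP with most counts of each locus only, strong calls only, shares of 90% or 70%, DESeq2 1.42.0 (in the joint fit and as size factors), and 1 strain effect for both sets. Added after the data were seen were the joint fit with all its alternatives, leaving out SNP positions listed under 2 loci, leaving out YW, strong calls taken 5 times from the median ratio, and the storage list's median total over members measured in both sets. Shares carry Wilson 95% intervals. Where an allele had no read, the limit given is the share that 3 counts would make. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. They take each count as a separate read, so at loci with several SNPs they can be too narrow. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.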

Results

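The study made 2 sets of reciprocal crosses between japonica and indica rice to find imprinted genes of the endosperm, that is, genes whose expression depends on which parent an allele came from. Reads at SNPs between the parents were counted per allele in LR, RL, YW and WY, with the replicate libraries of a cross pooled (3, 3, 2 and 2). The tables hold 62102 SNPs in 12299 loci for LR-RL and 59107 SNPs in 12378 loci for YW-WY. Reads summed over SNPs came to 29714227 in LR, 34433249 in RL, 29149713 in YW and 29302004 in WY. The loci with enough counts to be tested numbered 10867 in LR-RL and 11443 in YW-WY. The median tested locus had 394 counts in LR, 375 in RL, 387 in YW and 265 in WY. Since replicates are pooled, values below carry counting error and no spread between replicates.

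Endosperm receives 2 maternal genomes and 1 paternal genome, and the maternal share of the typical locus lay near that dosage in LR but above it in YW. The median share over tested loci was 67.1% (95% interval from the ranked loci 66.9 to 67.3) in LR and 63.8% (63.5 to 63.9) in RL. It was 75.1% (74.9 to 75.3) in YW and 62.9% (62.7 to 63.2) in WY, against 66.7% for 2:1. Over all reads the maternal share was 67.2% in LR, 62.3% in RL, 77.6% in YW and 60.7% in WY. The japonica mother thus gave the higher share in both sets. SNPs with the Liuqianxin allele as the reference allele had a median share of 68.3% in LR and 62.5% in RL. SNPs with the Rongfeng allele as reference had 63.2% and 68.2%, so the median leaned to the reference allele. Over pooled reads the shares in LR and RL were 67.2% and 62.2% at the former SNPs and 66.4% and 63.2% at the latter. Differences between crosses were not tested against replicates.

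In LR-RL, maternally expressed loci included genes whose paternal allele was near or below detection in both directions of the cross. LOC_Os06g30280 (chromosome 6, SNPs from 17470885 to 17471475), annotated as an expressed protein, had 0 paternal reads of 1146 in LR, which allows a share of up to 0.262%, and a maternal share of 99.9% in RL. LOC_Os11g40530 (chromosome 11, 24181054 to 24181378), the lipid transfer protein family member LTPL162, was 99.9% maternal in LR (Wilson 95% interval 99.9 to 99.9) and in RL (99.6 to 100). The basic leucine zipper gene LOC_Os04g10260 (chromosome 4, 5539589 to 5545454) was 99.9% maternal in both crosses, and the cupin gene LOC_Os08g08960, of a family that includes seed storage proteins, was 99.8% maternal in LR and 99.9% in RL. MBTB15 (LOC_Os08g03470), with a BTB domain, had 0 paternal reads of 993 in LR, which allows up to 0.302%, and 99.9% maternal reads in RL. The other loci farthest toward the mother were LOC_Os02g33700, LOC_Os05g30000, LOC_Os09g38429, LOC_Os12g17710 and LOC_Os05g10800, all annotated as expressed or hypothetical proteins.

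Paternally expressed loci of LR-RL were led by OsYUCCA11 (LOC_Os12g08780, chromosome 12, 4515689 to 4517287), a flavin monooxygenase of auxin synthesis. Its maternal share was 0.0483% in LR (0.00853 to 0.273) and 0.385% in RL (0.177 to 0.837). The F-box genes OsFBX370 (LOC_Os10g05500), OsFBX364 (LOC_Os10g04900) and OsFBX32 (LOC_Os01g69940), which encode putative substrate adaptors of ubiquitin ligases, had maternal shares of at most 2.02%. OsFBX370 had 0 maternal reads of 178 in LR and 0 of 134 in RL, which allow up to 1.69% and 2.24%. The NAC transcription factor gene LOC_Os11g31360 (chromosome 11, 18301380 to 18303465) was 0.0901% maternal in LR (0.0555 to 0.146) and 3.62% in RL (2.83 to 4.61). The CTP synthase gene LOC_Os12g36950 was 1.24% maternal in LR and had 0 maternal reads of 278 in RL, which allow up to 1.08%. The MYB gene LOC_Os02g17190, the SWP gene LOC_Os08g24420, the kinase gene LOC_Os02g57080 and LOC_Os01g68820 completed the 10 loci farthest toward the father. Reads of F-box, NAC and SWP genes can be shared with their paralogs, so the locus behind such counts is uncertain.

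In all, 92 loci of LR-RL had strong maternal and 177 strong paternal calls. The median share of the strong maternal calls was 99.8% in both crosses, and that of the strong paternal calls was 5.56% in LR and 6.82% in RL. With weaker departures included, 219 maternal and 734 paternal calls were made among the 10867 loci, so 22.98% of parental calls were maternal. Against the median ratio of each cross in place of 2:1, there were 321 maternal and 613 paternal calls (34.4% maternal). Loci at least 5 times from that ratio, a criterion added after the data had been seen, numbered 93 maternal and 169 paternal. With only the SNP with most counts of each locus, there were 144 maternal and 466 paternal calls. Of the SNPs at strong loci with at least 20 reads in each cross, 99.8% (maternal) and 99.9% (paternal) lay on the side of the call.

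**Figure D1:**
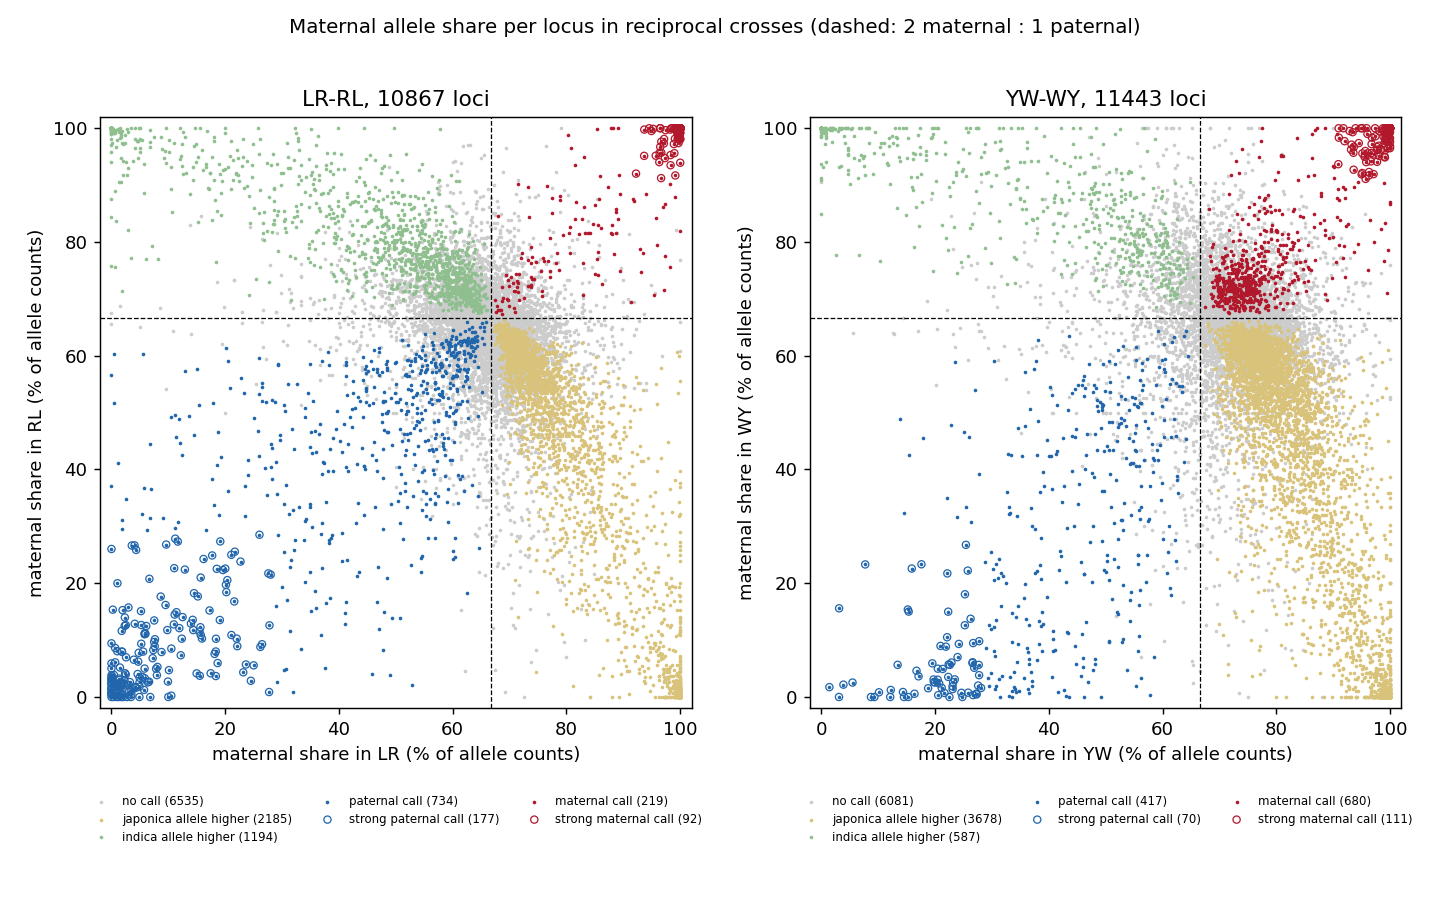
Each point is a tested locus, placed by its maternal share (% of allele counts) in the japonica-mother cross (x axis) and in the indica-mother cross (y axis) of LR-RL (left, 10867 loci) and YW-WY (right, 11443 loci); colours give the call and circles the strong calls. Loci with strong maternal calls (92 and 111) lie in the upper right corner, and those with strong paternal calls (177 and 70) lie at the lower left, farther right in YW than in LR.

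In YW-WY, the maternally expressed loci again included the leucine zipper gene LOC_Os04g10260, with a share of 99.6% in YW (99.4 to 99.7) and 99.9% in WY (99.8 to 100), and LTPL162 (LOC_Os11g40530), with 99.7% and 99.8%. The NAC gene LOC_Os05g34310 (chromosome 5, 20308609 to 20310218) was 99.7% maternal in YW and 99.6% in WY. A peroxidase gene, LOC_Os11g10460, was 99.8% maternal in YW and had 0 paternal reads of 197 in WY, which allow up to 1.52%. The Bet v I family gene LOC_Os04g39150 was 99.6% and 99.9% maternal. The zinc finger gene LOC_Os05g23950 and the Pong-type transposon locus LOC_Os02g26740 had no paternal read in either cross, which allows up to 2.01% and 1.84% in YW. LOC_Os02g28580, LOC_Os11g27470 and LOC_Os05g10800, annotated as expressed proteins, were at least 99.4% maternal in YW.

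The paternally expressed loci of YW-WY were led by LOC_Os05g48560, an expressed protein with a maternal share of 3.12% in YW (1.87 to 5.17) and 0 maternal reads of 242 in WY, which allow up to 1.24%. The CTP synthase gene LOC_Os12g36950 was 8.74% maternal in YW (6.38 to 11.9) and had 0 maternal reads of 254 in WY. The NAC gene LOC_Os11g31360 was 1.43% maternal in YW (1.26 to 1.62) and 1.74% in WY (1.21 to 2.48). At the calcium-dependent kinase family gene LOC_Os07g42770 the share was 15.3% in YW, and at the DNA methyltransferase gene LOC_Os05g04330 it was 24.8%, with no maternal read in WY at either. The F-box genes LOC_Os10g37540 and OsFBX371 (LOC_Os10g05520) had 9.35% and 10.1% in YW. The cornichon gene LOC_Os12g32180 had 33.5%, LOC_Os01g68820 had 16.4% and the BAK1-like receptor kinase gene LOC_Os01g17250 had 20.6% in YW. In WY these had 0 maternal reads of 318 (up to 0.943%), 0.572% and 0.325%.

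In YW-WY there were 111 strong maternal and 70 strong paternal calls. The median share of the strong paternal calls was 21.8% in YW and 3.31% in WY, while that of the strong maternal calls was 99.2% in YW and 99.1% in WY. All departures together gave 680 maternal and 417 paternal calls among 11443 loci, 62.0% of them maternal. This split depended on the null. Against the median ratio of each cross there were 378 maternal and 630 paternal calls (37.5% maternal), of which 240 maternal and 384 paternal calls were shared with those against 2:1. Loci at least 5 times from the median ratio numbered 101 maternal and 124 paternal, so the strong paternal count depended on the null as well. With only the SNP with most counts, maternal calls numbered 383. Of the SNPs at strong loci with at least 20 reads in each cross, 99.1% (maternal) and 100% (paternal) lay on the side of the call.

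The sets shared most of their strong maternal loci and, seen from YW-WY, nearly all strong paternal ones. Among 9753 loci tested in both sets, 70 had strong maternal calls in both, of 79 in LR-RL and 83 in YW-WY, where 0.672 would be met by chance (Fisher's exact test, p = 9.51e-154). Strong paternal calls in both numbered 60, of 159 in LR-RL and 63 in YW-WY, where chance gives 1.03 (Fisher's exact test, p = 6.54e-109). Taken 5 times from the median ratio of each cross, 68 maternal and 106 paternal loci were shared. The shared maternal loci with the largest departures were LOC_Os02g28580, LOC_Os04g10260, LTPL162, LOC_Os04g39150, LOC_Os05g10800, LOC_Os05g34310, LOC_Os11g10460, LOC_Os06g30280, LOC_Os08g08960 and LOC_Os02g26740. The shared paternal loci were LOC_Os12g36950, LOC_Os11g31360, LOC_Os07g42770, LOC_Os05g48560, LOC_Os05g04330, LOC_Os01g68820, LOC_Os01g17250, OsFBX371, the NAC gene LOC_Os11g31340 and the cytochrome b5-like gene LOC_Os09g16520. Calls of any size were shared at 144 loci (maternal, of 194 and 621, chance 12.4) and 340 loci (paternal, of 674 and 392, chance 27.1). With YW left out, the strong paternal share of LR-RL was met in WY at 154 of 159 loci (96.9%), and the strong maternal share at 73 of 79. Of the 674 paternal calls of LR-RL, 573 had an adjusted p under 0.05 (exact binomial test) and a share below 2:1 in WY. A single cross does not separate parent from strain. The median tested locus of WY already lay below 2:1, at 62.9%, so these 573 are not replicated calls.

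The strong paternal loci of LR-RL differed in level in YW alone. Over the 159 loci, the median maternal share was 5.25% in LR, 6.09% in RL, 5.86% in WY and 31.7% in YW (bootstrap 95% interval 30.3 to 33.9). The share was higher in YW than in WY at 153 of the 159 loci, and 94 of the 99 loci that were not strong in YW-WY missed the required share in YW only. The 79 strong maternal loci of LR-RL had a median share of 99.2% in YW and 99.0% in WY.

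**Figure D2:**
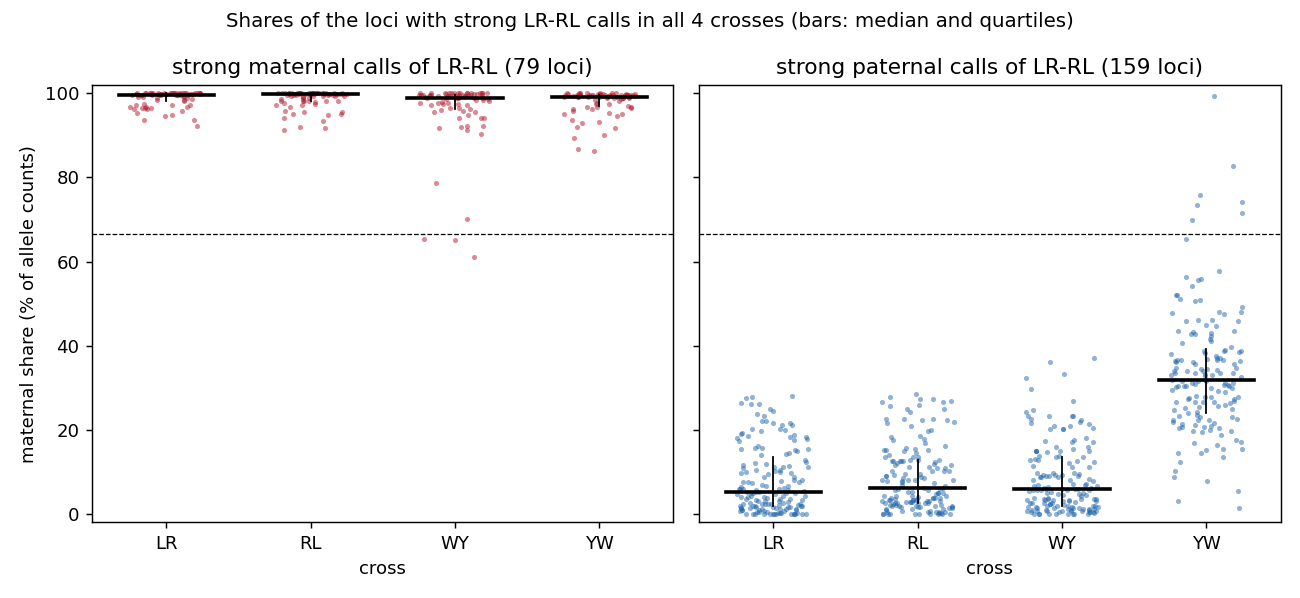
Maternal share (% of allele counts, y axis) in each of the 4 crosses (x axis) of the loci with a strong maternal (left, 79) or strong paternal call (right, 159) in LR-RL that were tested in both sets; each point is a locus, bars mark medians and vertical lines quartiles. The paternal loci have medians of 5.25% in LR, 6.09% in RL, 5.86% in WY and 31.7% in YW.

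A joint edgeR fit, chosen after the data had been seen, took the 2 cross sets as replicates and called 249 maternal and 653 paternal loci of 9753. It called all 70 maternal and all 60 paternal loci that were strong in both sets. The fit used the same pooled counts as those calls, so this overlap is no independent support. Its p-values rest on 1 residual degree of freedom per locus and on a spread pooled over loci. Of the calls of any size shared by both sets it held 132 of 144 maternal and 333 of 340 paternal. The log2 departure from 2:1 in this fit was 8.04 at LTPL162 (LOC_Os11g40530, adjusted p = 3.23e-127, edgeR) and -7.65 at the NAC gene LOC_Os11g31360 (adjusted p = 6.09e-124, edgeR), each in the same direction in 4 of 4 crosses. A single strain effect for both sets gave 148 and 353 calls.

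Parent-of-origin effects of the sets were related across loci, with a Pearson r of 0.84 and a Spearman rho of 0.42 over 9753 loci, which are not independent replicates. Strain effects had a Pearson r of 0.80 and a Spearman rho of 0.66. The median departure from 2:1 was -0.07 (log2) in LR-RL and 0.17 in YW-WY. A difference between the sets passed the counting test at 4187 loci, with 3822 more maternal in YW-WY and 365 more maternal in LR-RL. With only the SNP with most counts these were 2082 and 140. This test covers counting error only, so it does not show a difference beyond the spread between replicates, and YW had the raised share of 75.1% at its median locus.

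Many loci followed the strain of the allele in both directions of the cross. In LR-RL the japonica allele was higher at 2185 loci and the indica allele at 1194, and against the median ratio of each cross at 1751 and 1543. The japonica allele was the reference allele at 60045 of the 62102 SNPs of LR-RL, so a bias toward the reference allele was not separated from this japonica excess. A cellulase gene, LOC_Os05g15510, had 0 maternal (indica) reads of 4816 in RL, which allows up to 0.0623%, and LOC_Os10g22100, LOC_Os05g04215, LOC_Os01g37350 (a retrotransposon protein) and LOC_Os03g10310 were likewise read almost only from the japonica allele. On the indica side stood an O-methyltransferase gene, LOC_Os11g19880, with 0 maternal reads of 1481 in LR (up to 0.203%) and 99.8% in RL, the MLA7-like gene LOC_Os11g27440, LOC_Os08g13130, LOC_Os01g36820 and the plastocyanin-like gene LOC_Os02g06690. In YW-WY the japonica allele was higher at 3678 loci and the indica allele at 587, but against the median ratio of each cross the numbers were 1998 and 1515. The japonica allele was read almost alone at LOC_Os05g04215, the glycosyl hydrolase gene LOC_Os11g47550, LOC_Os01g12780, the peptide transporter gene LOC_Os01g68510 and the tic21 gene LOC_Os02g09470. The indica allele was read almost alone at PROLM29 (LOC_Os12g17010, 0.0675% maternal in YW and 99.9% in WY), LOC_Os08g06920, LOC_Os04g51480, the ABC transporter gene LOC_Os01g50100 and LOC_Os11g19880. Among loci tested in both sets, 1582 had japonica calls and 367 indica calls in both. A locus missing from the genome of a parent, or whose reads do not align, would count here in the same way as an allele that is not transcribed.

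Genes of Polycomb repressive complex 2, which silences genes by methylating histone H3, included strongly and moderately maternal members. OsFIE1 (LOC_Os08g04290, chromosome 8, 2095910 to 2096042) was 99.7% maternal in LR (99.3 to 99.9) and 99.5% in RL (97.1 to 99.9), and 98.9% in YW and 98.5% in WY. OsEMF2a (LOC_Os04g08034) was 91.7% and 87.5% maternal in LR and RL, and 92.2% and 82.8% in YW and WY. OsFIE2 (LOC_Os08g04270) had 67.2% and 65.9% with no call in LR-RL. Its shares of 76.0% in YW and 70.7% in WY gave a call that was lost against the median ratio and with the SNP with most counts. OsCLF and OsiEZ1 had no maternal call in either set. Maternal calls numbered 2 of 6 members in LR-RL (Fisher's exact test, adjusted p = 0.0230) and 3 of 5 in YW-WY (adjusted p = 0.0158), the set with the median share of 75.1% in YW. In the joint edgeR fit the adjusted p was 1.13e-69 for LOC_Os08g04290 and 2.73e-12 for LOC_Os04g08034, with the same direction in 4 of 4 crosses.

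Among DNA methylation genes, paternal calls stood out in LR-RL, at 4 of 9 members (adjusted p = 0.0158, Fisher's exact test). OsMET1b (LOC_Os07g08500), a maintenance DNA methyltransferase, had a maternal share of 11.2% in LR (9.35 to 13.3), 49.5% in RL (47.1 to 52.0), 22.9% in YW and 47.8% in WY. OsAGO4b (LOC_Os04g06770), an Argonaute of RNA-directed DNA methylation, had 28.3%, 38.4%, 40.4% and 42.4%. The calls at OsROS1a (60.2% and 59.8%) and OsDDM1b (51.9% and 50.3%) were lost with the SNP with most counts alone. In YW-WY 2 of 9 members had paternal calls, OsMET1b and OsAGO4b, which did not pass (adjusted p = 0.129, Fisher's exact test). No member had a maternal call in either set.

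Of 3 auxin synthesis genes, OsYUCCA11 and OsTAR1 were paternal in both sets. OsTAR1 (LOC_Os05g07720), a tryptophan aminotransferase of the step before OsYUCCA11, was 1.61% maternal in LR (1.33 to 1.93) and 1.51% in RL (1.14 to 1.99). In YW-WY the shares were 23.1% in YW and 1.38% in WY for OsTAR1, and 24.6% and 0.733% for OsYUCCA11. OsYUCCA9 (62.2% in LR and 64.3% in RL) had a small paternal call that was lost against the median ratio and with the SNP with most counts alone. In YW-WY it had no call (77.9% in YW and 64.9% in WY), and against the median ratio it was called maternal. Paternal calls numbered 3 of 3 in LR-RL (Fisher's exact test, adjusted p = 0.00982) and 2 of 3 in YW-WY (adjusted p = 0.0207). Strong paternal calls numbered 2 of 3 in both (exact adjusted p = 0.0125 and 0.00353), with OsYUCCA11 and OsTAR1 below 2:1 in 4 of 4 crosses.

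Sugar import genes included the sucrose transporter gene OsSWEET11 (LOC_Os08g42350). It had 0 paternal reads of 267 in LR and of 129 in RL, and was 99.9% maternal in YW and 99.1% in WY. Its counts in LR and RL lay below those of the median tested locus (394 and 375). RNA of maternal seed tissue could give such shares as well, and was not separated from endosperm RNA at this gene. SUS3, a sucrose synthase, had small maternal departures of 68.4% in LR, 68.1% in RL, 71.7% in YW and 67.5% in WY. In YW-WY its call was lost with the SNP with most counts, and against the median ratio the indica allele was higher. OsSWEET15 was called in YW-WY (81.1% and 77.1%), a call lost with the SNP with most counts. Maternal calls numbered 2 of 6 in LR-RL (Fisher's exact test, adjusted p = 0.0230) and 3 of 6 in YW-WY (adjusted p = 0.0207). Strong maternal calls numbered 1 of 6 in each set (Fisher's exact test, adjusted p = 0.303 in both).

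Storage protein genes and their regulators had maternal calls at 3 of 10 members in LR-RL (Fisher's exact test, adjusted p = 0.0140) and 2 of 8 in YW-WY (adjusted p = 0.226). NF-YC12, a transcription factor subunit, was 80.8% maternal in LR, 96.6% in RL, 77.4% in YW and 97.7% in WY. The glutelin gene GluB4 was 92.9% and 78.8% maternal in LR and RL. RPBF, a DOF factor that binds prolamin promoters, was 89.4% and 74.9% maternal in LR-RL, but in YW-WY (94.6% and 38.8%) the japonica allele was higher. GluA3 was called maternal in YW-WY (78.3% and 68.8%), and GluA1 and GluA2 followed the japonica allele in both sets, except that in YW-WY GluA1 was called maternal against the median ratio. Starch synthesis genes had maternal calls at 1 of 12 members in LR-RL (exact adjusted p = 0.578) and 3 of 8 in YW-WY (exact adjusted p = 0.0332). SSIIIa was 73.8% maternal in LR and in RL, 83.7% in YW and 71.0% in WY. SBE1 (80.7% and 69.3%) and ISA1 (74.9% and 71.9%) were called in YW-WY. The YW-WY call of SSIIIa was lost with the SNP with most counts, and that of ISA1 against the median ratio. Wx, the granule-bound starch synthase, followed the indica allele, with 12.2% in LR and 95.03% in RL.

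Over the lists, 9 pairs of list and direction passed with calls of any size and 2, both auxin synthesis, with strong calls. Loci with more counts reach a call at smaller departures, and the lists were not matched to the other loci by counts. SUS3, for example, was called with 451634 counts in LR, against 394 at the median tested locus. The list tests with calls of any size therefore do not separate a list effect from depth. Counts adjusted over the list alone equalled those over all loci, except for 1 paternal call against 0 among storage genes in LR-RL. None of the 5 listed endosperm MADS-box genes, 4 nucellus and ovule markers or 3 embryo markers was in the tables. Of 9 photosynthesis markers of green pericarp, RBCS2 had a maternal share of 46.7% in LR, 78.3% in RL, 50.3% in YW and 69.4% in WY, and PsbP followed the indica allele in LR-RL. The aleurone markers OLE18 and OLE16 had no parental call, with 59.0% and 63.1% in LR and 70.8% and 71.7% in RL.

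**Figure D3:**
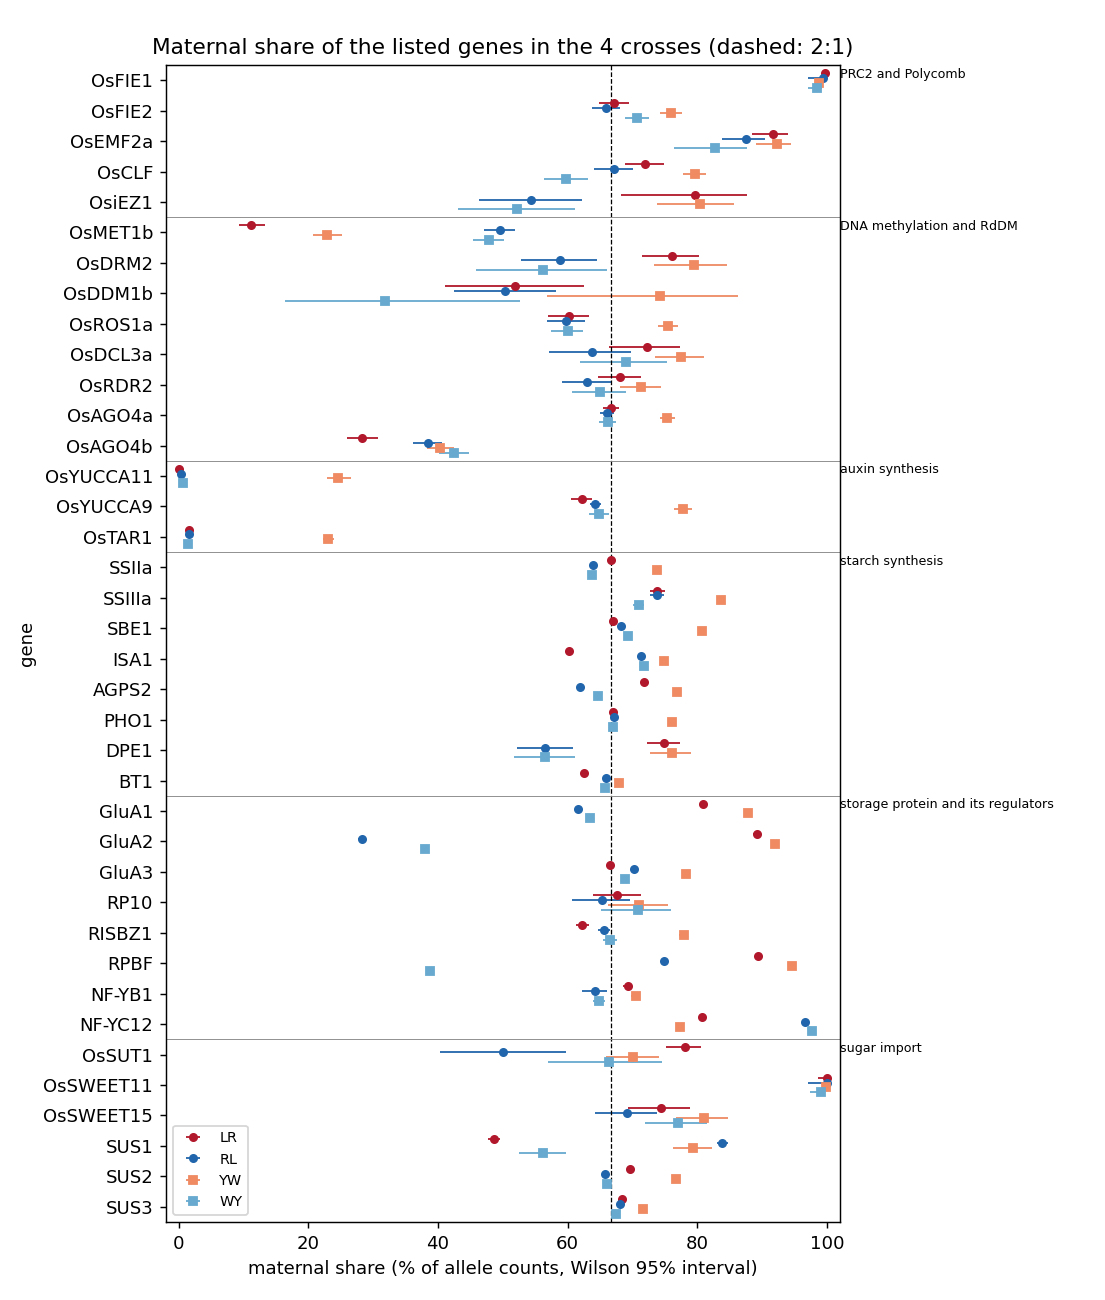
Maternal share (% of allele counts, x axis) of the listed genes tested in both sets (y axis) in LR, RL, YW and WY, with Wilson 95% intervals; the dashed line is the 2:1 share. OsFIE1 and OsSWEET11 lie at or above 98.5% in each cross, while OsYUCCA11 and OsTAR1 lie at or below 1.61% in LR, RL and WY and at 24.6% and 23.1% in YW.

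Total counts compare hybrids that share nuclear parents but differ in which parent was the mother, and so in which strain's allele is present in 2 copies. A locus read mostly from the allele of 1 strain, such as Wx, can therefore differ in total through dosage alone. The folds were not corrected for this. In LR-RL, prolamin storage protein genes were far higher in RL: PROLM16 (LOC_Os05g26720) by 72.7-fold (counting interval 68.0 to 77.8), PROLM18 by 58.3-fold, PROLM14 by 44.7-fold, PROLM1 by 39.3-fold and PROLM17 by 36.0-fold. Glutelin genes were also higher in RL, GluA1 by 3.64-fold, GluB1 by 3.52-fold and GluA3 by 3.11-fold, as was Wx by 2.54-fold. Higher in LR were LTPL162 by 18.4-fold (17.6 to 19.3), LOC_Os12g27940 by 15.6-fold, the glyoxalase gene LOC_Os03g16940 by 15.6-fold, the lipase gene LOC_Os01g46220 by 14.6-fold and the DnaK gene LOC_Os05g38530 by 14.1-fold. Among listed genes, the sucrose transporter OsSUT1 was 9.11-fold higher in LR (7.39 to 11.3), NF-YB1 7.33-fold and OsFIE1 6.07-fold. The aleurone markers OLE16 and OLE18 were 8.42-fold and 7.92-fold higher in LR, and the pericarp markers RBCS2 and PsbP 2.81-fold and 1.65-fold. A total of 202 loci were at least 4-fold higher in LR and 112 in RL. The storage list had a median log2 ratio of LR over RL of -1.04 over 10 members, at the 0.08 percentile of 10000 random lists of like abundance. Over the 8 members measured in both sets, a choice made after the data had been seen, it was -0.36, at the 16.8 percentile. None of these differences could be tested against replicates.

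In YW-WY, the DUF581 gene LOC_Os07g42390 was 38.6-fold higher in YW (33.7 to 44.5), LOC_Os08g28960 17.6-fold, the antimicrobial peptide gene LOC_Os11g37270 12.7-fold, LOC_Os10g32680 12.4-fold and LOC_Os10g31330 11.04-fold. Higher in WY were a cytochrome P450 gene, LOC_Os02g38940, by 22.99-fold (20.9 to 25.3), PROLM14 by 14.8-fold, LOC_Os02g31030 by 12.9-fold, the O-methyltransferase gene LOC_Os11g19880 by 12.7-fold and LTPL36 (LOC_Os03g25350) by 12.3-fold. Among listed genes OsTAR1 was 3.83-fold and OsSUT1 3.33-fold higher in YW, while RPBF (3.20-fold), SUS3 (3.11-fold), SUS2 (2.90-fold) and AGPS2 (2.61-fold) were higher in WY. At least 4-fold higher were 118 loci in YW and 91 in WY. The storage list had a median log2 ratio of YW over WY of 0.46 over 8 members, at the 99.96 percentile of random lists. The aleurone markers OLE16 and OLE18 were 2.07-fold and 1.70-fold higher in YW, and the pericarp marker RBCS2 2.27-fold. Requiring a mean of 50 counts left 86 and 52 loci in LR-RL and 52 and 52 in YW-WY.

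**Figure D4:**
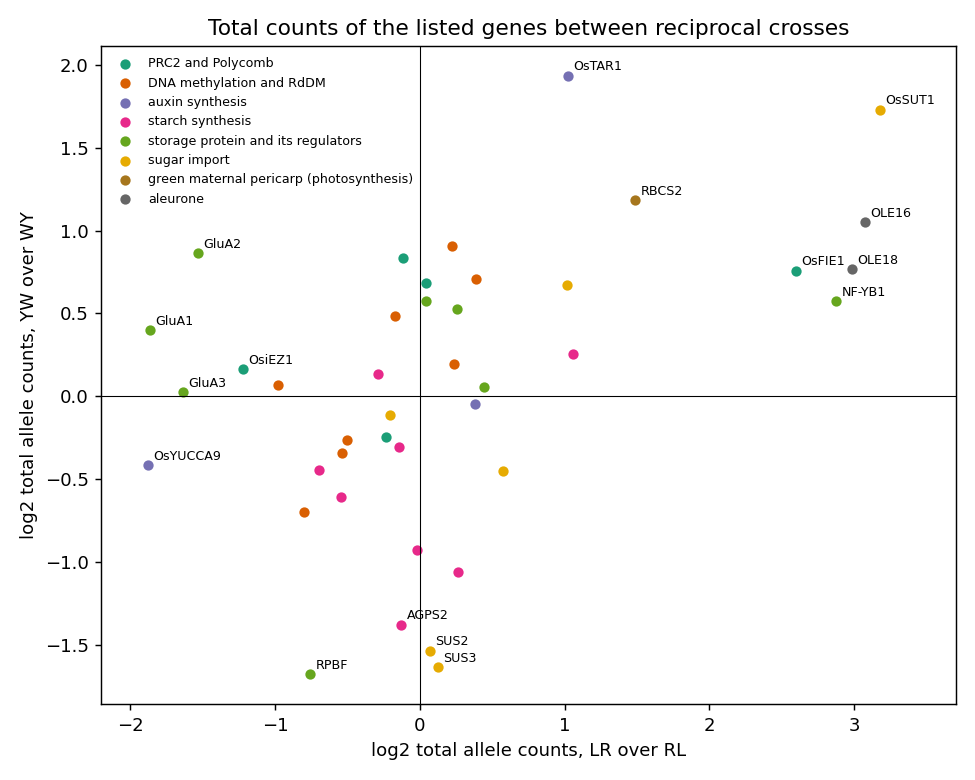
Log2 ratio of total allele counts (both alleles, TMM-scaled) of the listed genes and markers, LR over RL (x axis) against YW over WY (y axis); each point is a gene tested in both sets, coloured by list. OsSUT1 and OLE16 are higher in the japonica-mother cross of both sets, and GluA1 is higher in RL but also higher in YW.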

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

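The difference between the sets was a comparison fixed before the data were examined, listing the loci with opposite calls was chosen afterwards, and no explanation was tested for it. At 4 loci the calls of the sets pointed in opposite directions, paternal in LR-RL and maternal in YW-WY, and 0 loci showed the reverse. The difference between the sets was not tested against replicates, since the counts are pooled. The parent-of-origin effect in LR-RL minus that in YW-WY was -0.48 on the log2 scale at LOC_Os01g38620, annotated as an exonuclease, -1.02 at LOC_Os03g31839, annotated as a transposon protein, -0.35 at LOC_Os03g41419, which holds a serpin domain, and -0.62 at LOC_Os04g40300, annotated as a transglutaminase. The maternal shares of LOC_Os01g38620 were 64.7% in LR, 65.0% in RL, 75.3% in YW and 68.6% in WY. Those of LOC_Os03g31839 were 61.7%, 62.3%, 81.2% and 71.8% in the same order. LOC_Os03g41419 had 65.1%, 65.7%, 73.4% and 67.9%, and LOC_Os04g40300 had 59.6%, 60.1%, 69.9% and 69.4%. The median share of all tested loci was 75.1% in YW, against 67.1% in LR. None of the 4 loci had a strong call in either set.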

How the results depend on the processing

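The joint fit with its alternatives, the removal of SNP positions listed under 2 loci, the removal of YW, strong calls taken 5 times from the median ratio and the storage list's median over shared members were chosen after the data had been seen; the other alternatives of this part were fixed before. No paired analysis was possible because the columns carry no replicate numbers. For the same reason leaving out replicates, a replicate block, and DESeq2 or size factors for the allele calls within a set were not run, and the inbred controls (SNP quality, absent-parent share, their total counts) were not analysed here. Of 140 alternative values of the main counts and shares, 103 stayed within their margin (1.5 times a count, or the interval of a share) and 37 did not. The 103 include values that could hardly change by design. These are the strong counts against the median ratio and the joint fit with DESeq2 size factors (again 249 and 653), which its terms per cross absorb. The cause was not tested unless stated. With only the SNP with most counts, LR-RL had 144 maternal, 466 paternal, 1321 japonica and 773 indica calls, and YW-WY 383 maternal and 2450 japonica calls. That setting uses fewer counts per locus and counts no read at several SNPs of a locus. It also gave 140 and 2082 loci more maternal in LR-RL and in YW-WY, and median shares of 64.0% in RL and 63.4% in WY. Against the median ratio, YW-WY had 378 maternal, 630 paternal, 1998 japonica and 1515 indica calls; this setting changed the null of both crosses at once. Strong calls are 5 times from 2:1 there too, so their unchanged counts test nothing; taken 5 times from the median ratio, 124 paternal calls were strong in YW-WY and 106 in both sets. A mean of at least 50 counts, which tests fewer loci, left 56 strong maternal calls in LR-RL and 46 in both sets, a median share of 63.2% in WY, and 86, 52, 52 and 52 loci with 4-fold totals (higher in LR, RL, YW and WY). Strong calls, fewer by construction, numbered 92 maternal and 177 paternal in LR-RL, and 111 and 70 in YW-WY. Shares of 90% or 70% gave 93, 185, 117 and 78 in the same order. Strong calls left 2 pairs of gene list and direction of 9. With YW left out, 573 paternal and 154 strong paternal calls of LR-RL were met by WY alone, a single cross that does not separate parent from strain. Over the 8 storage list members measured in both sets, the median log2 ratio of LR over RL was -0.36. With 1 strain effect the joint fit called 148 maternal and 353 paternal loci. Of the alternative values of single named loci, 605 kept the call or stayed without 1, 24 lost the call, 11 gained 1, 8 moved and 3 reversed. Reversed against the median ratio were the strain effects in YW-WY of BT1 (LOC_Os02g10800, -0.35 log2), NF-YB1 (LOC_Os02g49410, -0.23) and SSIIa (LOC_Os06g12450, -0.075). Depth limits the absent allele to 2.01% at 149 reads (LOC_Os05g23950 in YW) and to 0.262% at 1146 reads (LOC_Os06g30280 in LR).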

Other observations

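The annotation groups, the prolamin family and the tests of reference allele bias, of Yu6-type endosperm, of Yu6 seed tissue and of maternal seed tissue were chosen after the results had been seen. The tests of weaker silencing and of paralogs were written before their values were computed, though the counts and annotations of single loci with strong calls had been seen. Genes annotated with the word kinase, which include kinases of small molecules such as LOC_Os01g73450 (amino acids) and LOC_Os08g41790 (uridine), were over-represented among strong paternal calls, with 22 of 177 in LR-RL (7.75 expected, Fisher's exact test, adjusted p = 0.000938 over 100 tests) and 10 of 70 in YW-WY (3.14 expected, adjusted p = 0.0264). F-box genes made up 12 of the strong paternal calls in LR-RL (4.51 expected, exact adjusted p = 0.0382) and 6 in YW-WY (1.74 expected, exact adjusted p = 0.128). NAC genes made up 4 in LR-RL (0.440 expected, exact adjusted p = 0.0264), all from the chromosome 11 cluster between 18288381 and 18313628. Of these, 2 were strong in YW-WY (exact adjusted p = 0.180). Fisher's test counts neighbouring paralogs as independent, so the NAC result does not show enrichment of the family beyond this cluster. Neighbouring F-box genes, such as OsFBX370 and OsFBX371, are counted in the same way. Loci annotated only as expressed proteins made up 36 of 92 strong maternal calls in LR-RL (20.5 expected, exact adjusted p = 0.0173) and 33 of 111 in YW-WY (25.2 expected, exact adjusted p = 0.606).

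Prolamin genes, which encode alcohol-soluble seed storage proteins, had higher total counts in the indica-mother cross at 10 of 10 measured members in LR-RL and 10 of 10 in YW-WY, without a test against replicates. The median fold was 18.1 in LR-RL and 4.05 in YW-WY, and 8 and 5 members were at least 4-fold higher. Between the same crosses, most measured pericarp and aleurone markers moved the other way. The pericarp marker RBCS2 was 2.81-fold higher in LR and 2.27-fold higher in YW, and PsbP was 1.65-fold higher in LR. RBCS2 was only 46.7% maternal in LR and 50.3% in YW, so its higher totals there do not show more maternal pericarp. The aleurone markers OLE16 and OLE18 were 8.42-fold and 7.92-fold higher in LR and 2.07-fold and 1.70-fold higher in YW. The aleurone gene OsCR4 was 1.37-fold higher in WY. Tissue make-up, developmental stage and allele dosage were not separated from the cross. The allele shares of the prolamin genes did not follow a single pattern. PROLM16 followed the japonica allele in LR-RL, with a maternal share of 97.49% in LR and 20.1% in RL, and was strongly maternal in YW-WY, with 95.7% in YW and 91.1% in WY. PROLM14 followed the indica allele in both sets. These genes are close paralogs, so which locus each read came from is uncertain.

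The first pattern is the raised maternal share in YW of loci that were paternal in the other 3 crosses. Reference allele bias is argued against by its size, since the median YW share of the 159 loci was 31.7% (30.3 to 33.9), far above the shift of a few points between SNPs of either reference allele, which could be measured in LR-RL only. Within YW-WY, a bias of equal size at all loci would change the odds of a maternal read between YW and WY by the same factor everywhere. The odds of the median share instead differed by 7.46 times at these loci and by 1.73 times at loci without a parental call. How far such a bias varies between loci was not measured. Endosperm of Yu6 type in the YW pools is a candidate explanation. The 159 loci gave a median share of such endosperm of 25.9% (22.2 to 27.8), with quartiles over loci of 17.4% and 33.8%. With LR shares as the baseline, this predicted a median YW share of 76.0% at the 8885 loci without a parental call. The observed value missed it by -0.763 points. With the 2:1 dosage as baseline the prediction was 75.3% (missed by -0.0948 points), and with the WY shift mirrored about 2:1 it was 77.4% (missed by -2.22 points). Weaker silencing of maternal Yu6 alleles stays open as well, because the relative total count of the 159 loci rose by 0.24 log2 (0.14 to 0.34). This lies between no rise and the 0.43 of fully added maternal transcripts. Yu6-type endosperm alone was predicted to raise these totals little or not at all. The interval excludes both no rise and the full 0.43, but it covers the spread over loci and none between libraries. The totals therefore leave both explanations undecided. RNA of Yu6 seed tissue could not be excluded either, with 5.66% of the loci within 5 points of their WY share, since no list of transcripts of that tissue was tested; the labels describe pollen-sterile mothers and pipetting meant to avoid such tissue, and these explanations cannot be told apart here.

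The second pattern is the strong maternal calls, which RNA of maternal seed tissue could also give. In LR-RL the midpoint of the median shares of LR and RL at loci without a parental call was 65.9%, or -0.73 points from 2:1. A large share of such RNA would have moved it toward the mother. Choosing loci without a call leaves out those moved far toward the mother in both crosses. Over all tested loci the medians were 67.1% in LR and 63.8% in RL. The midpoint of YW and WY at the loci without a parental call in LR-RL was 69.4%, or 2.76 points toward the mother. Such RNA therefore stays open in YW-WY beside the explanations of the YW shares given above. The photosynthesis markers decide nothing here. RBCS2 (46.7% in LR, 78.3% in RL) and PsbP (16.7% in LR, 93.8% in RL) followed the indica allele in LR-RL, and LOC_Os11g13890, below the minimum count, had 34 of 34 maternal reads in YW and 5 of 11 in WY. In LR-RL a small share in genes that the endosperm hardly transcribes stays open, because the listed nucellus and ovule markers were not in the tables. It stays open for OsSWEET11 too, whose 267 reads in LR and 129 in RL were all maternal. Maternal silencing or activation as such was not tested apart from RNA of maternal seed tissue.

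The third pattern is that strong calls of 1 direction lay beside each other. In LR-RL 21 pairs of neighbouring tested loci were both strongly paternal (2.86 expected). Reads shared between paralogs are argued against as the whole cause by the 13 pairs with differing annotation (1.72 expected, permutation p = 1e-05, the smallest that 100000 permutations can give). Annotations were compared as whole names, so numbered members of 1 family counted as differing. OsFBX364 beside OsFBX365 and OsFBX370 beside OsFBX371 were therefore among the 13, while the other pairs joined unlike annotations. The same count was 3 pairs among maternal calls in YW-WY (0.632 expected, permutation p = 0.025). These include POEI14 with POEI15 and PROLM16 with PROLM17, each pair of 1 family, so this count does not argue against shared reads. Among paternal calls of YW-WY the count was 3 pairs (0.249 expected, permutation p = 0.0021). There 2 of the 5 neighbouring pairs of any annotation had overlapping SNP ranges. Among maternal calls of LR-RL the count was 1 pair, POEI14 with POEI15 (permutation p = 0.37), which decides nothing. Pairs met in both sets include the pollen Ole e I genes POEI14 and POEI15 on chromosome 10, and shared regulation or shared transcripts of neighbours may both play a part and were not tested apart.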
